A study of Mus musculus with 8 samples.

How the data were processed

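Total RNA from the border zone of 8 mouse hearts was isolated with Trizol, selected for poly(A), made into libraries and sequenced on an Illumina HiSeq2000 in paired reads of 100 bases, per the labels' protocols. Per the submitters' processing notes the genome build was mm9 and the tools were TopHat2 2.0.5, Cufflinks 2.0.2, HTSeq 0.5.4p2 and DESeq, whose settings and roles are not given in the sources used here. Whether the libraries keep the strand of the RNA is not given either. The deposited table holds 1 normalised signal per locus and sample for 35299 loci, and a deposited annotation lists the exons of each locus with its mm9 coordinates. In every sample all values were whole multiples of the sample's smallest step, within 0.000001, so each value is a read count divided by 1 size factor per sample. Multiplying back gave the reads per locus: 141, 143, 161 and 108 M reads for Sham replicates 1 to 4, and 190.2, 176, 167 and 165 M reads for MI replicates 1 to 4. A signal of 1 read is worth between 0.663 and 1.58 normalised reads. A count of 0 allows up to 3 reads, which is 1.99 to 4.73 normalised reads. Such floors and the 95% intervals given for loci of few reads cover counting error only and leave out differences between animals. The intervals pool the reads of each group. No molecular identifiers are described for the reads, so copies of 1 molecule could not be told from separate molecules.

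Groups were taken from the sample titles, which match the treatment given among the sample characteristics. Other fields conflict with them: the source field of the MI samples names Sham, and some descriptions name a sham infarct for MI samples or an infarct for a Sham sample. The series states 4 biological replicates per condition, and no pair of libraries was a duplicate (chi-square per degree of freedom of their read counts within a group between 35.2 and 155, where sampling noise gives about 1).

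Loci carry assembly numbers and UCSC gene identifiers in place of gene symbols. The reference used here for names, GENCODE release M21, is on another build, so no coordinate was carried over. A locus was named where lengths of its exons and introns equalled those of a GENCODE gene on the same chromosome and strand. The start positions in the builds served only to check order, as a name was dropped where their offset lay 200000 bases or more from the median of neighbouring loci. Of 20506 annotated loci with more than 1 exon, 19375 (94.5%) were named, 17001 as protein-coding and 2191 as non-coding. Decoys made by lengthening 1 intron of each structure by 1 base gave 104 names in order, 0.537% of the names given. The 5593 annotated loci of 1 exon stayed unnamed, and 432 loci that hold exons of more than 1 gene were kept out of the gene lists, with 33 list members lost in this way. The 9200 loci whose transcripts the deposited annotation classes as intergenic, antisense or other are called unannotated. Of these, 287 match a gene of the later GENCODE release. All coordinates are those of the deposited annotation, in mm9, counted from 1.

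The main test was limma 3.58.1 with an intensity trend (R 4.3.3) on log2(value + 1) of the deposited signal, MI against Sham, 2-sided, over the 19186 loci with a mean of at least 10 over the 8 samples, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p given for a locus is from this fit unless another tool is named. Log2 differences are on this scale with the moderated standard error, and the pseudocount of 1 understates the change of low loci. Levels are mean ± SD with n = 4, and a value after ± beside a log2 difference is its standard error. Whole libraries were compared by exact permutation tests, loci of different classes by Fisher's exact test and neighbouring loci by Spearman correlation with 10000 shuffles of the pairing. Before the data were examined, 37 gene lists were fixed, with 602 members of which 534 had a locus of their own and 512 were tested. Lists with at least 3 tested members (36) were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. With the preset correlation 20 lists were higher and 4 lower in MI, and no call held with an estimated correlation, where the smallest adjusted p was 0.218 and 7 lists had an unadjusted p under 0.05.

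The genes named in the text were chosen by a rule fixed before the data were examined: a set of infarct and non-coding genes, the 3 called members of each list with the largest change (or, where none was called, the member with the smallest p), and the 5 largest rises and 5 largest falls among annotated genes with a mean of at least 50 and among unannotated loci with a mean of at least 10, both with groups that do not overlap. Some genes that this rule picks are not reported here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the rest. The rebuilt reads were also tested with edgeR 4.0.16 (quasi-likelihood, TMM), DESeq2 1.42.0 and voom; all of the values came out whole, and edgeR called 7937 loci against 7854 in the main test, 7601 of them shared. Other alternatives were pseudocounts of 0.5 and 5, no filter or a mean of at least 50, TMM, upper-quartile and total scaling, a robust fit, a fold of at least 1.2 as the null hypothesis, the replicate number as a block, leaving out each library, and, added after the data were seen, scaling to the total outside chrM, thinning to equal depth and restricting unannotated loci by distance.

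The fits were tested on simulated reads for this comparison with 200 of 19092 tested loci changed. The main test recovered 43.9% of 1.5-fold, 74.6% of 2-fold and 83.6% of 4-fold changes. Of its 142 calls 4.93% were unchanged loci, against 4.23% for edgeR, 4.26% for voom and 19.9% for DESeq2. The simulated share of changed loci was far below the 40.9% called in the data, which makes the adjusted threshold stricter. For the main test the simulated reads were divided by their true size factors. The rates therefore say nothing on scaling and need not hold for the real comparison.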

Results

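Long RNA was sequenced from the hearts of 8 adult mice, 4 after a sham operation and 4 after myocardial infarction (MI), the death of heart muscle that follows a blocked coronary artery. Per the labels, the animals were C57BL/6J mice 12 weeks old. The tissue was the border zone, the rim of muscle next to the infarct or its counterpart in sham animals, taken 2 weeks after surgery. The series is described as profiling of non-coding RNA, so the comparison asks which long RNAs, coding, non-coding or absent from the annotation, differ between infarcted and sham hearts. The libraries held between 108 and 190.2 M reads in loci. All 4 MI libraries were deeper than all 4 Sham libraries (175 ± 11.3 against 138 ± 21.8 M reads, mean ± SD, n = 4 each; 2-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give; Benjamini-Hochberg p = 0.0333 over 7 library measures). Spearman correlations over the tested loci ran from 0.988 to 0.992 within Sham, from 0.989 to 0.994 within MI and from 0.965 to 0.980 between the groups. The leading principal component held 61.9% of the variance and parted the groups, with the library of MI replicate 2 at 34.8 against 62.4 to 63.2 for the other MI libraries and -65.2 to -42.6 for Sham.

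Infarcted hearts held more RNA of the genes Nppa, Postn and Spp1 and less of Atp2a2 than sham hearts. Nppa, which encodes atrial natriuretic peptide (mm9 chromosome 4, 147374210 to 147380693), rose from 17713 ± 1464 to 372116 ± 80824 normalised reads (mean ± SD, n = 4 each; log2 difference 4.37 ± 0.16 SE, limma adjusted p = 2.76e-07). Postn, the matricellular protein periostin (chromosome 3, 54165047 to 54194954), rose from 5819 ± 1516 to 98308 ± 21169 (log2 difference 4.09 ± 0.21, adjusted p = 1.10e-06), and Spp1, the secreted glycoprotein osteopontin (chromosome 5, 104864140 to 104870062), from 39.8 ± 12.4 to 6935 ± 3915 (log2 difference 7.27 ± 0.36, adjusted p = 8.95e-07). Atp2a2, the calcium pump of the sarcoplasmic reticulum (chromosome 5, 122903523 to 122952355), fell from 2594632 ± 127312 to 1343825 ± 253218 (log2 difference -0.97 ± 0.16, adjusted p = 8.38e-04). In these 4 genes no MI library overlapped the Sham libraries.

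Over the genome, 3999 loci rose and 3855 fell in MI among 19186 tested (limma-trend, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes were uneven, with 1735 loci higher and 723 lower. Protein-coding genes made up 1313 of these rises and 231 of these falls, and unannotated loci 251 and 433. The MI and Sham values did not overlap for 7603 tested loci, 39.6%, where chance gives 2.86%. The split of calls stayed near even with TMM scaling (4284 higher and 3640 lower) and upper-quartile scaling (4175 and 3933). It was lost with scaling to the library total, which gave 8569 higher and 1493 lower. Scaling to the total outside the mitochondrial genome (chrM), an alternative added after the data were seen, gave 6389 and 2142. The total scalings, with and without chrM, shifted the median log2 difference by 0.31 and 0.19, and directions below are relative to the deposited scaling. Sham samples carry a reanalysis remark in their titles that MI samples lack, so a difference of origin and the effect of infarction cannot be told apart by these samples.

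**Figure D1:**
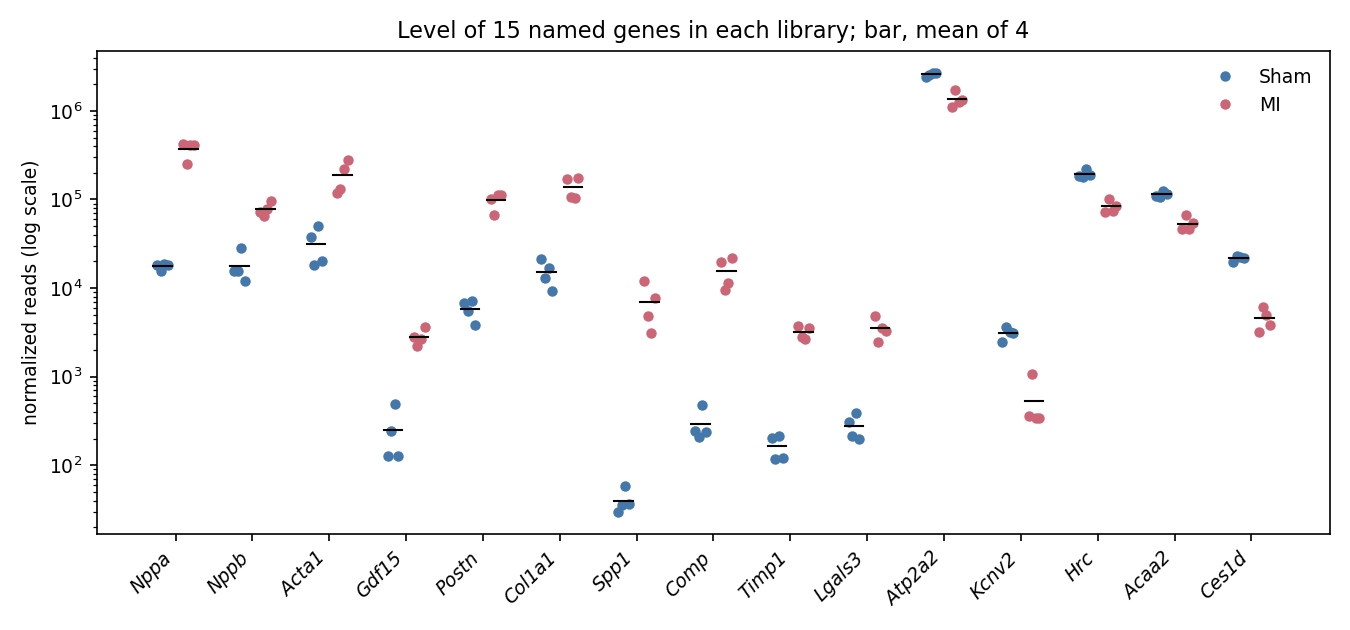
Normalised reads (vertical axis, log scale) of 15 named genes (horizontal axis) in each of the 4 Sham and 4 MI libraries, points being libraries and black bars group means. No MI library overlaps a Sham library in any of these genes, for instance 251068 to 418466 in MI against 15578 to 18866 in Sham for Nppa.

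Among genes of heart muscle, those of the fetal and stress programme rose and those of calcium handling and excitability fell. All 14 tested members of the fetal and stress list rose, adjusted over all loci or adjusted over the list alone (median log2 difference 1.36; camera adjusted p = 3.00e-09, and adjusted p = 0.227 with an estimated correlation). Besides Nppa, the largest rises were of Gdf15, a stress-induced cytokine of the TGF-beta family (log2 difference 3.70 ± 0.38, 11.2 times the Sham mean), and Acta1, skeletal alpha-actin (log2 difference 2.61 ± 0.35, 5.95 times). Nppb, which encodes B-type natriuretic peptide, stood at 17918 ± 7325 normalised reads in Sham and 77592 ± 12775 in MI (log2 difference 2.18 ± 0.22, adjusted p = 5.32e-05). Of 25 tested genes of calcium handling and ion channels, 18 fell and none rose, with 18 falls and 1 rise when adjusted over the list alone (median -0.64; camera adjusted p = 2.03e-06, and adjusted p = 0.275 with an estimated correlation). With total scaling 12 of them fell and 4 rose. Kcnv2, a modifying subunit of voltage-gated potassium channels, fell most (log2 difference -2.74 ± 0.32), followed by Kcnj3, an inward rectifier subunit (-1.33 ± 0.21), and Hrc, a calcium-binding protein of the sarcoplasmic reticulum (-1.21 ± 0.12). In the sarcomere and Z-disc list 4 of 20 members fell and 1 rose, also when adjusted over the list alone, and the list did not pass (median -0.15, 0.16 with total scaling; camera adjusted p = 0.0849, and adjusted p = 0.585 with an estimated correlation). The falls included the regulatory and essential ventricular myosin light chains Myl2 (-0.68 ± 0.11) and Myl3 (-0.53 ± 0.11) and the titin cap gene Tcap (-0.66 ± 0.10). Pdlim5, a Z-disc protein, rose (0.33 ± 0.08; singled out after its value was seen). Myh6 and Myh7, the alpha and beta myosin heavy chains, lie in 1 locus of the assembly and were not separable. That locus fell (-0.62 ± 0.17, adjusted p = 0.0128), with the call lost without Sham replicate 4 at -0.59. Cardiac transcription factors went both ways, with 5 of 12 lower and 1 higher (6 and 1 adjusted over the list alone; median -0.20, 0.11 with total scaling; camera adjusted p = 0.103, and adjusted p = 0.275 with an estimated correlation). Without a filter on low values the sarcomere and transcription factor lists passed as lower. Both also passed as lower with fry (adjusted p = 0.0476 and 0.0046). Hopx (-1.01 ± 0.10) and Tbx5 (-0.75 ± 0.12) fell and Tbx20 rose (0.68 ± 0.08).

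Genes of mitochondrial energy metabolism fell together. All 21 tested nuclear genes of oxidative phosphorylation fell (median log2 difference -0.60; camera adjusted p = 3.64e-10, and adjusted p = 0.275 with an estimated correlation). All 15 of the tricarboxylic acid cycle fell too (median -0.58; camera adjusted p = 1.35e-08, and adjusted p = 0.275 with an estimated correlation). In fatty acid oxidation 19 of 21 fell and 1 rose (median -0.78; camera adjusted p = 4.19e-09, and adjusted p = 0.275 with an estimated correlation). These counts were equal when adjusted over the list alone. With total scaling 20, 15 and 16 members passed as lower. Acaa2, the thiolase of the mitochondrial beta-oxidation spiral, fell from 114199 ± 7627 to 53370.1 ± 9957 (log2 difference -1.11 ± 0.12, adjusted p = 6.78e-05), Ucp3, an uncoupling protein, by a log2 difference of -1.02 ± 0.11 and Hadh, a hydroxyacyl-CoA dehydrogenase, by -0.98 ± 0.09. Log2 differences were -1.003 ± 0.137 for Cox7a1 and -0.74 ± 0.12 for Cox6a2, subunits of cytochrome c oxidase, and -0.80 ± 0.10 for Sdha of succinate dehydrogenase. In the cycle itself Suclg2 (-0.74 ± 0.08), Idh3b (-0.72 ± 0.10) and Suclg1 (-0.66 ± 0.09) fell most. The exception in fatty acid oxidation was Pdk4, a kinase that restrains pyruvate dehydrogenase, which rose (0.45 ± 0.10; singled out after its value was seen). Glycolysis genes divided, 5 higher and 6 lower of 19, also when adjusted over the list alone (median -0.04, 0.27 with total scaling; camera adjusted p = 0.398, and adjusted p = 0.799 with an estimated correlation). Pfkp, the platelet form of phosphofructokinase (1.16 ± 0.09), and the low-level Aldoc (1.23 ± 0.30) rose while Ldhb, a lactate dehydrogenase subunit, fell (-0.91 ± 0.10). Loci on chrM also fell in 6 of 8 cases, with log2 differences among these 6 between -0.99 and -0.54. The share of reads on chrM was 30.7 ± 1.33% in Sham and 24.9 ± 1.04% in MI (exact permutation p = 0.0286, 2-sided, lower in all 4 MI libraries; Benjamini-Hochberg p = 0.0333).

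Extracellular matrix genes rose almost without exception. All 20 tested collagen genes rose (median log2 difference 2.48; camera adjusted p = 1.75e-17, and adjusted p = 0.218 with an estimated correlation). Of 34 genes of matricellular and matrix glycoproteins 33 rose (median 2.53; camera adjusted p = 1.90e-23, and adjusted p = 0.218 with an estimated correlation). Col1a1, the alpha-1 chain of type I collagen, rose from 15063 ± 5132 to 138516 ± 38934 (log2 difference 3.22 ± 0.26, adjusted p = 1.20e-05). The fibril-associated or minor collagens Col11a1 (6.44 ± 0.36), Col8a2 (5.19 ± 0.27) and Col12a1 (4.83 ± 0.15) rose by more. Cthrc1, a secreted protein with a collagen-like repeat (6.02 ± 0.67), and Fmod, the proteoglycan fibromodulin (5.35 ± 0.26), followed Spp1 among the glycoproteins. In collagen processing and matrix proteases 22 of 25 rose and none fell (22 and 1 adjusted over the list alone; median 1.80; camera adjusted p = 3.05e-12, and adjusted p = 0.218 with an estimated correlation). The largest rises were of the collagen prolyl hydroxylase subunit P4ha3 (5.20 ± 0.58), the macrophage elastase Mmp12 (4.50 ± 0.42) and the metalloproteinase inhibitor Timp1 (4.32 ± 0.21). Genes best known from cartilage, bone and tendon rose in 9 of 11 cases (10 adjusted over the list alone; median 2.26; camera adjusted p = 3.83e-08, and adjusted p = 0.218 with an estimated correlation). Comp, cartilage oligomeric matrix protein, rose from 292 ± 127 to 15589.6 ± 6018 (log2 difference 5.73 ± 0.31, adjusted p = 1.28e-06), followed by Tnmd, tenomodulin (4.40 ± 0.26), and Cilp2 (4.31 ± 0.32). For the lists of collagens and glycoproteins the counts were equal when adjusted over the list alone.

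Signalling and cell type markers of the stroma rose in part. Of the TGF-beta pathway 11 of 15 rose and 1 fell (12 and 1 adjusted over the list alone; median 0.86; camera adjusted p = 4.83e-06, and adjusted p = 0.218 with an estimated correlation). Those that rose included Inhba, an activin subunit (2.02 ± 0.26), and the ligand Tgfb2 (1.91 ± 0.18). Ltbp1, a latent TGF-beta binding protein, fell (-0.34 ± 0.09; singled out after its value was seen). In the Wnt list 5 of 9 rose and none fell (5 and 1 adjusted over the list alone; median 2.09; camera adjusted p = 0.0034, and adjusted p = 0.275 with an estimated correlation). Those that rose are secreted modulators of Wnt signalling, with Sfrp2 (4.58 ± 0.36), Dkk3 (3.96 ± 0.18) and Frzb (3.13 ± 0.17) at the head. Fibroblast markers rose in 7 of 8 cases and fell in 1, also adjusted over the list alone (median 0.93; camera adjusted p = 3.30e-04, and adjusted p = 0.218 with an estimated correlation). Meox1, a transcription factor of activated fibroblasts, rose from 1509 ± 447 to 7671 ± 1555 (log2 difference 2.37 ± 0.20), followed by Mgp, matrix Gla protein (1.97 ± 0.14), and Pi16 (1.67 ± 0.14). The member that fell was Dpep1 (-0.57 ± 0.13; also singled out after its value was seen). Among myofibroblast and smooth muscle markers 5 of 10 rose and 2 fell, also adjusted over the list alone, and the list did not pass (median 0.18; camera adjusted p = 0.375, and adjusted p = 0.712 with an estimated correlation). Cnn1, calponin (1.25 ± 0.20), Tagln, transgelin (0.89 ± 0.12), and Cald1, caldesmon (0.67 ± 0.09), rose. Pericyte markers rose in 2 of 7 cases, also adjusted over the list alone (median 0.10; camera adjusted p = 0.5, and adjusted p = 0.786 with an estimated correlation), namely Mcam (0.77 ± 0.11) and Cspg4 (0.60 ± 0.20, adjusted p = 0.0322). The call of Cspg4 ended in 5 of the 8 fits that left out a library, with the value lowest, 0.47, without MI replicate 4.

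Markers of immune cells rose across lineages. For macrophages and monocytes 20 of 24 rose and none fell (20 and 1 adjusted over the list alone; median 1.14; camera adjusted p = 2.16e-08, and adjusted p = 0.275 with an estimated correlation). Lgals3, galectin-3, rose from 278 ± 90.4 to 3525 ± 961 (log2 difference 3.68 ± 0.24), followed by Gpnmb (3.29 ± 0.37) and the lipid-sensing receptor Trem2 (2.30 ± 0.25). Neutrophil markers rose in 5 of 6 cases (median 1.76; camera adjusted p = 0.0056, and adjusted p = 0.329 with an estimated correlation). Every tested member was highest in MI replicate 2. Another 5 members, Mpo, Elane, Ngp, Camp and Ltf, had means below 10 and were not tested. In no library did these exceed 20.3 normalised reads in Sham or 14.8 in MI, so the rise covers only part of the list. The largest rises were of S100a8 (2.57 ± 0.49) and S100a9 (2.12 ± 0.45), the subunits of calprotectin, and the low-level Mmp8 (2.20 ± 0.49). T and NK cell markers rose in 11 of 17 (median 1.24; camera adjusted p = 2.82e-04, and adjusted p = 0.275 with an estimated correlation). Their levels were low, as for Il7r, the interleukin-7 receptor, at 32.0 ± 10.1 in Sham and 173 ± 55.9 in MI (log2 difference 2.41 ± 0.29), Cd3d (2.37 ± 0.39) and Cd8a (1.92 ± 0.45). B cell markers rose in 7 of 8 (median 1.19; camera adjusted p = 0.0029, and adjusted p = 0.283 with an estimated correlation). Among them were Cd22 (1.72 ± 0.35), Ms4a1 (1.22 ± 0.44) and Jchain, the joining chain of secreted antibodies (2.22 ± 0.81, adjusted p = 0.0489). Jchain stood at 1453 in MI replicate 3 and at 64.2 to 113 in the other MI libraries. Its call ended without MI replicate 4 or any Sham library, and that of Ms4a1 in 6 of the 8 such fits. Both ended with voom, too, and without a filter on low values, that of Jchain also with pseudocount 5, upper-quartile scaling and the robust fit, and that of Ms4a1 also with reads thinned to equal depth. All 10 tested genes of MHC class II and dendritic cells rose (median 0.68; camera adjusted p = 7.27e-05, and adjusted p = 0.275 with an estimated correlation). The largest were Itgax (2.62 ± 0.33), Ccr7 (2.05 ± 0.37) and Flt3 (1.80 ± 0.28). For the neutrophil, T cell, B cell and MHC lists the counts adjusted over the list alone were 5, 11, 7 and 10 rises. With total scaling the neutrophil and B cell lists did not pass camera.

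Secreted mediators and cell cycle genes rose as well. Of 27 chemokines and cytokines 21 rose and 3 fell, also adjusted over the list alone (median log2 difference 1.41; camera adjusted p = 1.71e-06, and adjusted p = 0.218 with an estimated correlation). Il6, interleukin-6, rose from 2.24 ± 1.55 to 58.0 ± 23.8 (4.31 ± 0.51, adjusted p = 1.17e-04), Il1rn, the interleukin-1 receptor antagonist, by 4.17 ± 0.39, and Cxcl13, a B cell chemokine, by 3.52 ± 0.79. Cxcl13 stood at 639.9 in MI replicate 3 and at 45.1 to 51.5 in the other MI libraries. The members that fell were Ccl11 (-2.18 ± 0.29), Cxcl14 (-0.94 ± 0.23) and Cxcl12 (-0.53 ± 0.10), singled out after their values were seen. Interferon response genes rose in 10 of 13 cases (median 0.52; camera adjusted p = 2.82e-04, and adjusted p = 0.283 with an estimated correlation). They included the antiviral Mx1 (1.51 ± 0.21), Oasl2 (0.81 ± 0.15) and the transcription factor Irf7 (0.71 ± 0.14). Complement genes rose in 5 of 8 (median 0.74; camera adjusted p = 0.0074, and adjusted p = 0.283 with an estimated correlation). They included the receptor C3ar1 (1.18 ± 0.30), the inhibitor Serping1 (0.87 ± 0.11) and the protease C1ra (0.86 ± 0.12). Both lists had the same counts adjusted over the list alone, and with total scaling the complement list did not pass camera. In the cell cycle list 21 of 26 rose and 1 fell (23 and 1 adjusted over the list alone; median 1.40; camera adjusted p = 2.54e-08, and adjusted p = 0.283 with an estimated correlation). Ccnb1, cyclin B1, rose from 56.9 ± 28.6 to 383 ± 94.1 (2.89 ± 0.40), the mitotic kinase Cdk1 by 2.32 ± 0.33 and the checkpoint kinase Bub1 by 2.26 ± 0.35. The member that fell was Cenpf, a kinetochore protein (-1.55 ± 0.26; singled out after its value was seen). Immediate early genes did not pass as a list (3 of 8 higher, also adjusted over the list alone; median 0.71; camera adjusted p = 0.126, and adjusted p = 0.563 with an estimated correlation). Junb (0.91 ± 0.15), Fos (1.80 ± 0.49) and Egr1 (1.16 ± 0.40) were higher. The list passed without Sham replicate 3. The call of Fos ended with edgeR and DESeq2, and that of Egr1 with voom and the robust fit. The call of Egr1 also ended in 6 of the 8 fits without a library, its lowest value being 0.86 without MI replicate 4. Endothelial markers did not move as a list, with 1 of 14 higher and 2 lower, also adjusted over the list alone (median 0.12; camera adjusted p = 0.524, and adjusted p = 0.785 with an estimated correlation). Flt1, a VEGF receptor (-0.52 ± 0.10), and the water channel Aqp1 (-0.55 ± 0.14) fell and Erg was higher (0.31 ± 0.10, adjusted p = 0.0283, lost in 5 of the 8 fits without a library). With total scaling neither Flt1 nor Aqp1 passed.

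**Figure D2:**
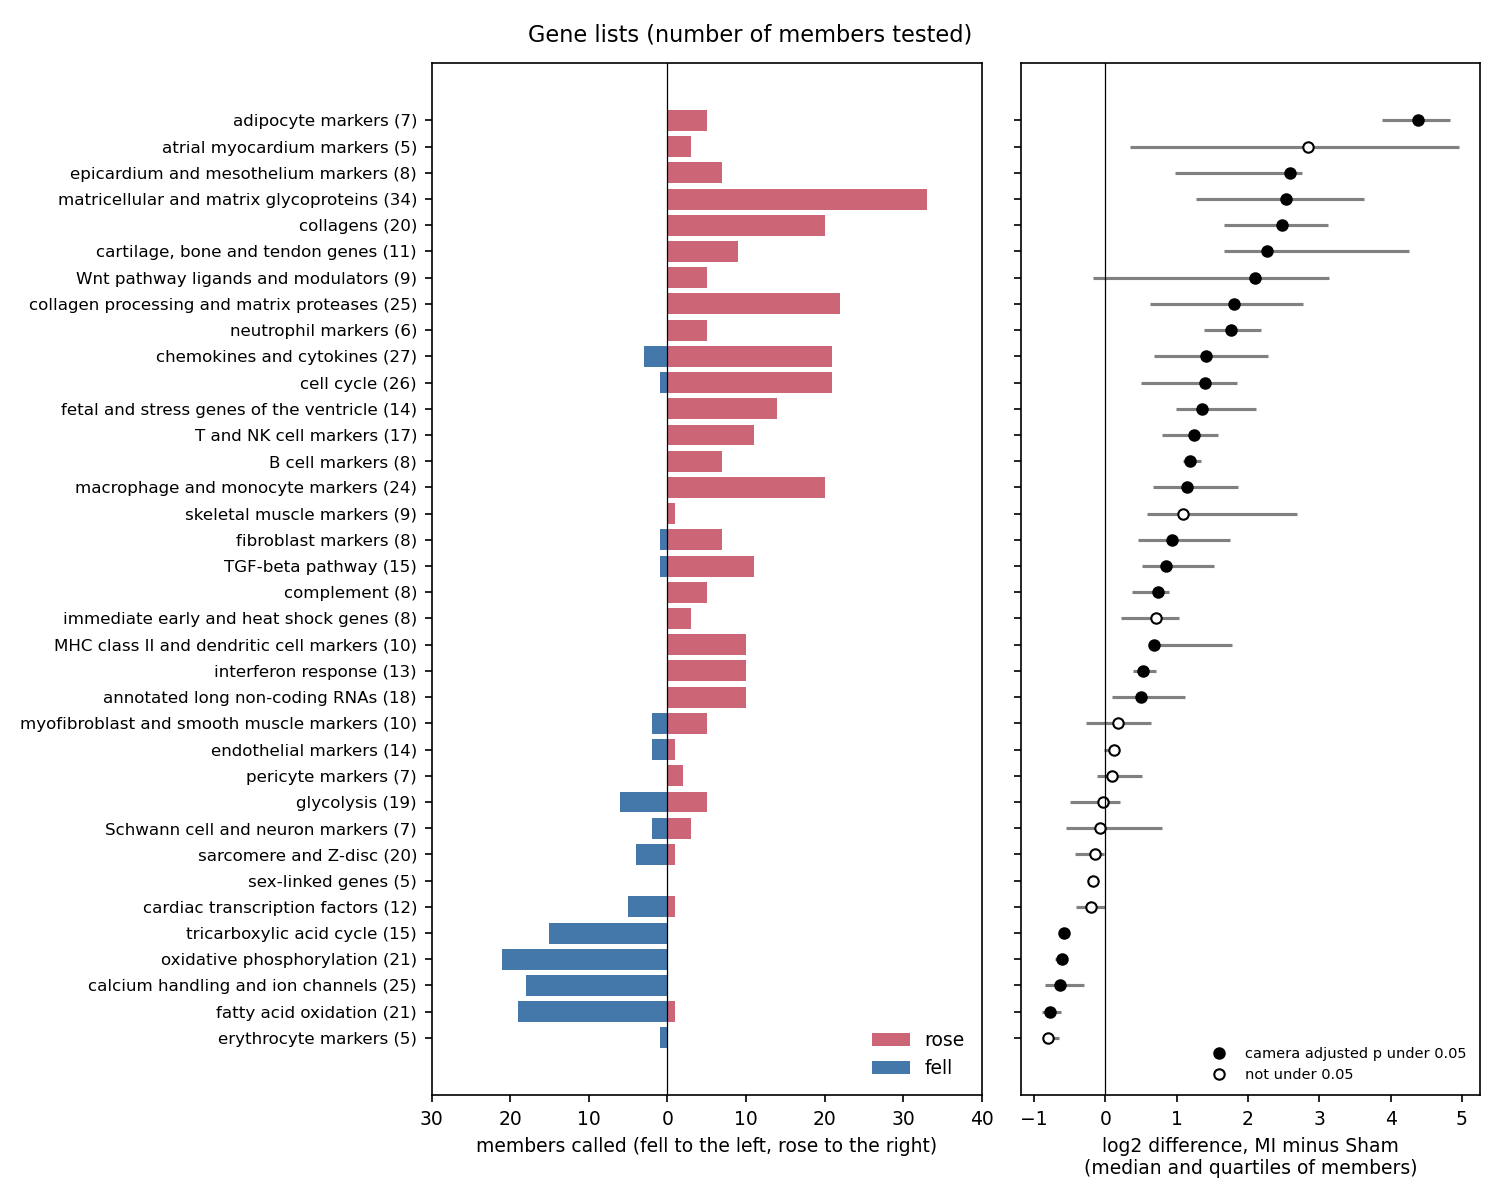
Left, members called higher (to the right) or lower (to the left) in MI for each gene list with at least 3 tested members, whose number stands in brackets. Right, the median (point) and quartiles (line) of the members' log2 differences, MI minus Sham, filled where camera's adjusted p was under 0.05. All 21 oxidative phosphorylation genes fell and all 20 collagens rose; with total scaling the median of the sarcomere, cardiac transcription factor, glycolysis, Schwann cell and sex-linked lists turns positive.

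Markers of tissues other than ventricular muscle differed widely between MI libraries. The atrial markers Sln, sarcolipin (log2 difference 5.25 ± 1.61), Myl7 (4.96 ± 1.66) and Myl4 (2.85 ± 0.79) were higher in MI, but MI replicate 1 held Myl7 at 9.94 and Sln at 1.33 normalised reads while MI replicate 2 held 4564 and 1387. The call of Myl7 ended in 6 and that of Sln in 4 of the 8 fits without a library, and those of Sln, Myl7 and Myl4 with the robust fit and with voom. The list had 3 of 5 members higher (4 adjusted over the list alone) and did not pass (median 2.85; camera adjusted p = 0.0801, and adjusted p = 0.275 with an estimated correlation). Without MI replicate 3 the count was 1, and without MI replicate 1 the list passed. The atrial list also passed as higher with fry (adjusted p = 0.0126). Adipocyte markers rose in 5 of 7 cases (6 adjusted over the list alone; median 4.39; camera adjusted p = 0.007, and adjusted p = 0.329 with an estimated correlation). Cfd, the fat-cell protease adipsin (4.97 ± 1.12), stood at 9299.5 in MI replicate 3 and between 98.6 and 1014 in the other MI libraries, and Car3 (4.89 ± 1.11) and Cidec (4.77 ± 1.002) showed the same library at the top. Without MI replicate 3 the list had 5 calls and a median of 3.29. With voom it had 0 calls, and edgeR gave 6 and DESeq2 5. With total scaling neither this list nor that of epicardium and mesothelium passed camera. Cidea was present in every library, at 2800.3 to 3777, so 1 member of this list is expressed by the heart samples themselves. Markers of epicardium and mesothelium, the lining of heart and body cavities, rose in 7 of 8 cases, also adjusted over the list alone (median 2.59, 1.71 without MI replicate 3; camera adjusted p = 0.0034, and adjusted p = 0.275 with an estimated correlation). Upk3b (3.33 ± 1.14), Upk1b (2.98 ± 0.79) and Lrrn4 (2.67 ± 0.86) were again highest in MI replicate 3. The call of Upk3b ended without that library, and also without Sham replicate 3 or 4, that of Lrrn4 without Sham replicate 4, and both with the robust fit. With voom the calls of Upk3b, Upk1b, Lrrn4 and Tnnt3 ended. Skeletal muscle markers had 1 of 9 members higher, also adjusted over the list alone, namely Tnnt3, fast troponin T (2.92 ± 0.74; median 1.09, -0.30 without MI replicate 3; camera adjusted p = 0.186, and adjusted p = 0.712 with an estimated correlation). In MI replicate 3 the fast myosin Myh4 reached 2716 and the calcium pump Atp2a1 3568, against at most 6.59 and 186 in any other library (both singled out after their values were seen).

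**Figure D3:**
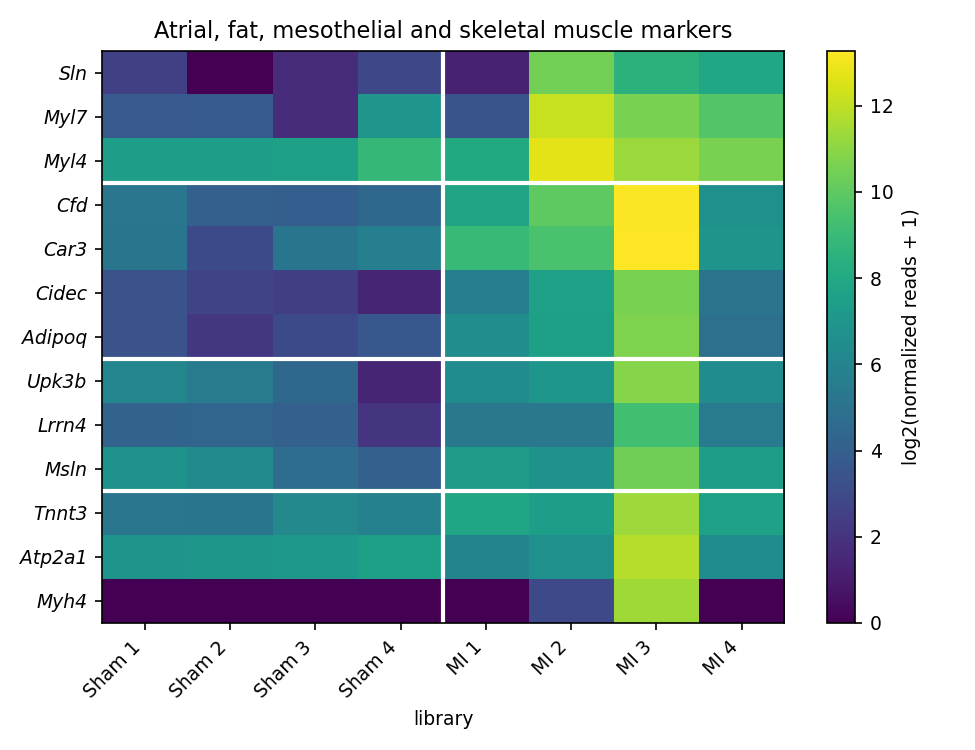
Level of 13 markers (vertical axis, in blocks for atrium, fat, mesothelium and skeletal muscle) in each library (horizontal axis), coloured by log2(normalised reads + 1). MI replicate 3 stands out in the fat, mesothelium and skeletal muscle blocks, as with Cfd at 9299.5 normalised reads, and MI replicate 1 lacks the atrial signal of the other MI libraries (Myl7 at 9.94).

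The lists of Schwann cell, erythrocyte and sex-linked genes did not pass camera. Schwann cell and neuron markers had 3 of 7 higher and 2 lower (3 and 3 adjusted over the list alone), with a median of -0.07, a mean of 0.10 and camera pointing up (camera adjusted p = 0.943, and adjusted p = 0.949 with an estimated correlation). Prph, peripherin (1.27 ± 0.27), and S100b (1.06 ± 0.32) were higher and the receptor Gfra3 lower (-0.98 ± 0.19), S100b losing its call in 4 of the 8 fits without a library and with reads thinned to equal depth. Erythrocyte markers had 1 of 5 lower (0 adjusted over the list alone; median -0.80; camera adjusted p = 0.128, and adjusted p = 0.563 with an estimated correlation), Alas2, the erythroid enzyme of heme synthesis (-0.80 ± 0.26, adjusted p = 0.0297), whose call ended in 5 of the 8 fits without a library, with both total scalings and with the robust fit. The erythrocyte list itself passed as lower with both total scalings, without Sham replicate 1 and without MI replicate 3. None of 5 sex-linked genes passed, over all loci or adjusted over the list alone (median -0.17; camera adjusted p = 0.141, and adjusted p = 0.441 with an estimated correlation). As a list they passed as lower with fry (adjusted p = 0.0414). Uty, from the Y chromosome, was at 3565 ± 231 in Sham and 3055 ± 269 in MI (log2 difference -0.22 ± 0.08, adjusted p = 0.0514). It passed as lower with upper-quartile scaling, the robust fit, DESeq2 and a mean of at least 50 and without MI replicate 2, and stood at 0.083 with total scaling. Ddx3y was at 8802 or more in every library, so no library lacked RNA of the Y chromosome. Of the lung markers only Sftpb, surfactant protein B, was tested and rose, from 16.9 ± 4.16 to 35.2 ± 5.29 normalised reads (1.03 ± 0.27), over all loci and adjusted over the list alone.

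Annotated genes with large rises and falls at a mean of at least 50 lay outside these lists in part. Spp1, Col11a1 and Col2a1, the alpha-1 chain of cartilage type II collagen (mm9 chromosome 15, 97805402 to 97835076), rose most. Col2a1 stood at 2.32 ± 2.68 normalised reads in Sham and 312 ± 69.0 in MI (log2 difference 7.02 ± 0.59, adjusted p = 1.81e-05). Cxcl3, a neutrophil chemokine (chromosome 5, 91215129 to 91217116), had no read in any Sham library and 106 ± 60.3 normalised reads in MI, at least 27.9-fold higher against a floor of 3 reads per Sham library. The predicted gene Gm6093 (chromosome 13, 33652617 to 33661186) also had no Sham read and 121 ± 139.6 in MI, at least 32.0-fold higher, or at least 13.6-fold without MI replicate 2. These floors cover counting error only. Large falls were those of Kcnv2, Cyp2b10, a cytochrome P450 (-2.47 ± 0.28), Clec18a, a C-type lectin (-2.33 ± 0.22), and Ces1d, a carboxylesterase of lipid metabolism (chromosome 8, 95689971 to 95721703). Ces1d fell from 21772 ± 1567 to 4548 ± 1303 (-2.30 ± 0.17, adjusted p = 8.40e-06). Cyp2b10, Ces1d and Mx1 have close paralogs, and how reads matching several genes were assigned is not given in the sources used here, so their levels are uncertain to that extent.

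In a fixed list of annotated long non-coding RNAs 10 of 18 tested members rose and none fell, also adjusted over the list alone (median log2 difference 0.49; camera adjusted p = 8.63e-04, and adjusted p = 0.229 with an estimated correlation). Miat (chromosome 5, 112642250 to 112657718) rose from 9.71 ± 1.44 to 48.5 ± 14.4 normalised reads (log2 difference 2.17 ± 0.27, adjusted p = 1.80e-04). Meg3 and Mirg, which share an imprinted cluster on chromosome 12, rose by 1.68 ± 0.15 and 1.61 ± 0.21. The wider class of annotated non-coding loci split evenly, with 134 higher and 130 lower of 848 tested. H19, an imprinted RNA, was at 1978 ± 689 normalised reads in Sham and 2674 ± 402 in MI (log2 difference 0.49 ± 0.23, adjusted p = 0.108). It passed with total scaling (log2 difference 0.80), with total scaling without chrM (0.68) and without Sham replicate 4 (0.66). Malat1 and Neat1 could not be named by exon structure and were not analysed here.

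Loci absent from the annotation were called less often than protein-coding genes, and falls made up more of their calls. Of 3908 unannotated loci tested, 371 rose and 652 fell, 26.2% called, against 3298 and 2919 of 13453 protein-coding genes, 46.2%, and 134 and 130 of 848 annotated non-coding loci, 31.1%. Unannotated loci were called less often than protein-coding genes (Fisher's exact test across loci, which are not independent replicates, adjusted p = 1.01e-114 over 3 pairs of classes). Falls made up 63.7% of calls at unannotated loci, 47.0% at protein-coding genes and 49.2% at annotated non-coding loci (Fisher's exact test, adjusted p = 5.64e-23 for unannotated against protein-coding and 0.489 for annotated non-coding against protein-coding). Per tested locus, 16.7% of unannotated loci fell and 9.49% rose, against 21.7% and 24.5% of protein-coding genes, all levels pooled. Unannotated loci were scarce, with a median of 25.3 normalised reads against 2201 for protein-coding genes. They also differed in structure: 67.9% of those tested had 1 exon, against 0% of the other classes, whose naming needed more than 1 exon. Of the 1256 tested unannotated loci with 2 or more exons, 160 rose and 367 fell. The gap in calling was not tested at equal exon number, so it may reflect exon number in part. The gap in calling held within the 3 bins of mean level from 10 to 200 (34.8% against 54.9% between 50 and 200, Fisher's exact p = 2.90e-18). It was not shown from 200 to 1000 (49.1% against 49.96%, Fisher's exact p = 0.799) and was turned round over 1000 (60.0% against 45.1%, p = 0.00915). The larger share of falls among calls held in the 4 bins up to 1000, for instance 73.6% against 16.97% of calls between 50 and 200 (Fisher's exact p = 6.52e-60), and was not shown over 1000 (68.8% against 62.2%, p = 0.374). From the lowest of the 5 bins to the highest, 8.68, 15.6, 25.6, 35.6 and 41.2% of tested unannotated loci fell, against 4.86, 7.19, 9.31, 11.5 and 28.1% of protein-coding genes. With total scaling 689 unannotated loci rose and 380 fell, and without MI replicate 1 226 rose and 598 fell. Without a filter on low values 701 rose and 725 fell. The gap to protein-coding genes in the share of falls was then 5.99 points, against 16.8 in the main test.

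**Figure D4:**
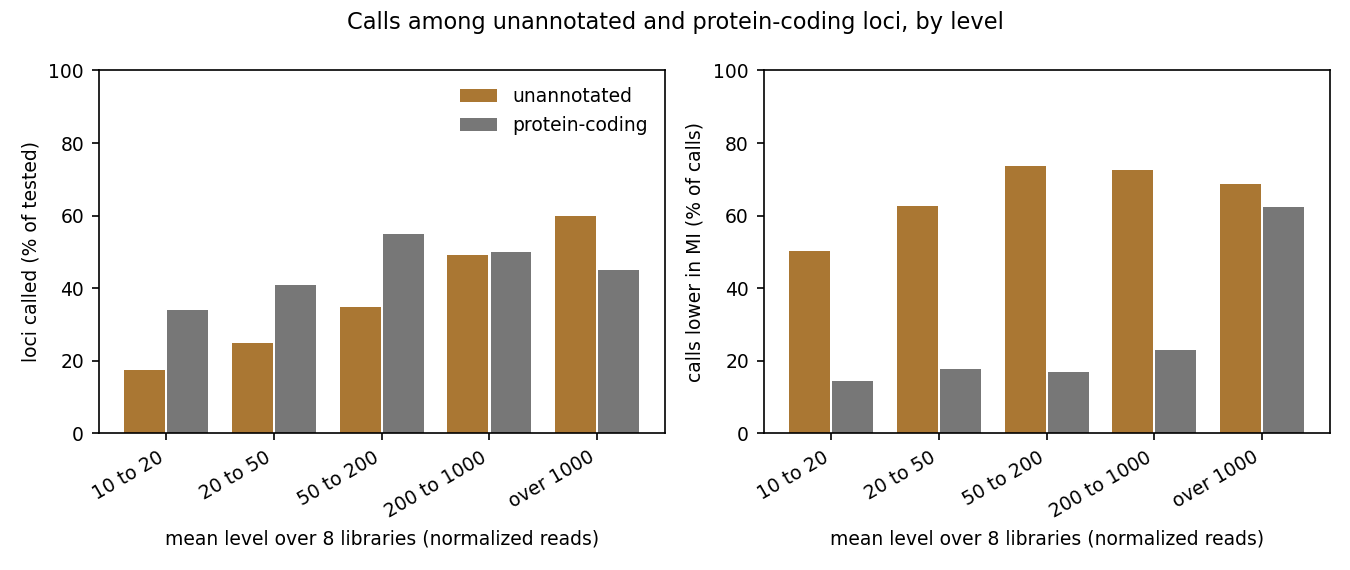
Percentage of tested loci called (left) and percentage of those calls that fell in MI (right) for unannotated loci and protein-coding genes, in 5 bins of mean level in normalised reads. Between 50 and 200 normalised reads 73.6% of calls at unannotated loci fell against 16.97% at protein-coding genes.

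The largest rise of an unannotated locus was at XLOC_016573, a locus of 1 exon with no strand given (mm9 chromosome 19, 37309611 to 37312196), which had 1 read in the 4 Sham libraries together and 497 ± 225 normalised reads in MI (1586 times, 95% exact binomial counting interval 284 to 62663; adjusted p = 5.34e-07). Its nearest tested protein-coding gene, March5, lay 10.4 kb away and was at a log2 difference of -0.20 ± 0.08 (adjusted p = 0.0858). XLOC_002924, of 4 exons on the minus strand (chromosome 10, 66959158 to 66998675), also had 1 Sham read and 36.6 ± 16.9 in MI (118 times, interval 20.95 to 4693), 1.94 kb from Egr2, a transcription factor gene that rose too (2.96 ± 0.31). XLOC_012723, of 6 exons (chromosome 17, 10057294 to 10089916), was the most abundant of the 5 at 34.3 ± 9.24 normalised reads in Sham and 672 ± 171 in MI (log2 difference 4.25 ± 0.24, adjusted p = 1.96e-06), 303 kb from Qk. Its exon structure matches the later GENCODE long non-coding RNA AC105304.1, and that of XLOC_007752 (4.91 ± 0.35) matches D030007L05Rik. XLOC_000120 (chromosome 1, 45073359 to 45085687) rose by 4.93 ± 0.65. The 5 largest falls were at XLOC_031775 (-3.11 ± 0.55), XLOC_001763 (-3.01 ± 0.41), XLOC_030914 (-3.00 ± 0.41), XLOC_023148 (-2.89 ± 0.46) and XLOC_000264 (-2.89 ± 0.31). The locus XLOC_031775, of 1 exon (chromosome 8, 88012974 to 88013772), lies 0.112 kb from Gpt2, an alanine aminotransferase gene that also fell (-1.35 ± 0.17). XLOC_000264 (chromosome 1, 80221554 to 80226147) fell from 136 ± 38.8 to 17.8 ± 6.71 and matches the later non-coding gene 2310015K22Rik. Strand use in counting is not given in the sources used here, so reads of overlapping genes on opposite strands cannot be assigned to either.

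Log2 differences of unannotated loci correlated with those of their nearest tested protein-coding gene, and the coefficient was largest within 10 kb. Over 3908 pairs the log2 differences correlated with a Spearman coefficient of 0.232 (permutation p = 0.0001, the smallest that 10000 shuffles give; 95% of shuffles between -0.032 and 0.031; Benjamini-Hochberg p = 0.000125 over 15 correlations). The correlation is across loci, which are not independent replicates. The coefficient was 0.410 for the 2049 pairs within 10 kb, 0.119 for the 1859 farther apart and 0.116 for the 642 over 100 kb (permutation p = 0.0024, Benjamini-Hochberg p = 0.00277). Among the 2639 pairs on opposite strands or at least 5 kb apart it was 0.172 (permutation p = 0.0001). On the same strand it was 0.124 over 451 pairs (permutation p = 0.0079), on opposite strands 0.279 over 824, and 0.237 where the locus has no strand. Pairs of a protein-coding gene and its nearest protein-coding gene, taken the same way, gave 0.129 in all, 0.141 within 10 kb and 0.054 over 100 kb (permutation p = 0.0902). The differences between these correlations were not tested. Whether reads running over from the neighbouring gene raise the coefficient at short distance was not tested either.

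**Figure D5:**
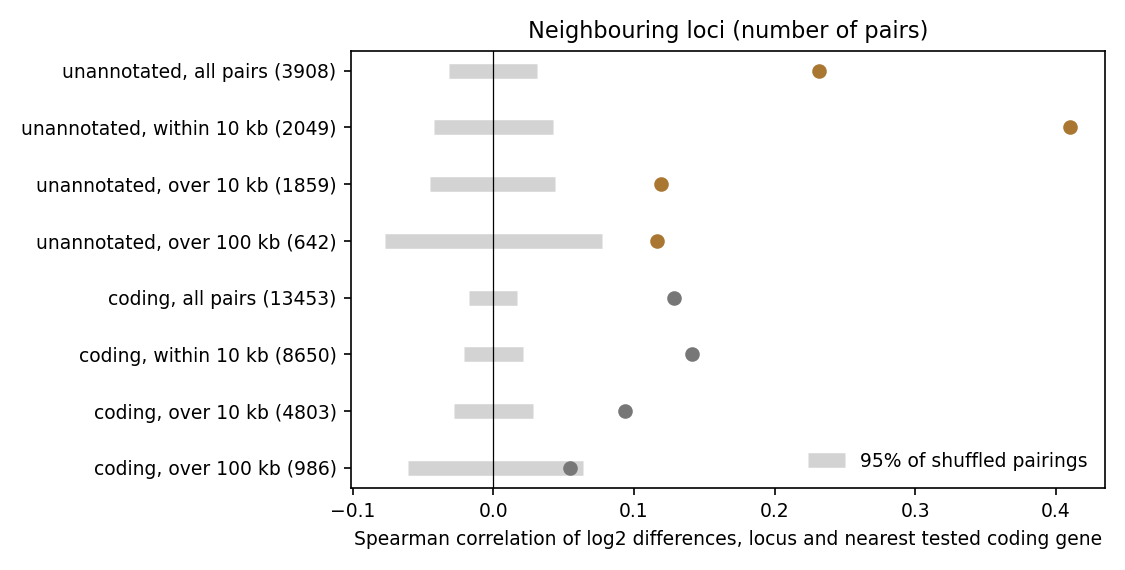
Spearman coefficient (horizontal axis) between the log2 differences of a locus and of its nearest tested protein-coding gene, for unannotated loci and for protein-coding genes by distance, with the number of pairs in brackets; grey bars hold 95% of 10000 shuffled pairings. It is 0.410 for unannotated loci within 10 kb and 0.141 for protein-coding genes within 10 kb.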

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

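Of the tests in this part, those of sequencing depth, of atrial tissue as the source of Nppa (reworded at that point), of oxidative phosphorylation transcripts, of marker order without some genes and of splits of the samples were chosen after the result was seen. A library was singled out where its gap to the nearest other of its group exceeded the 95% critical share of the group's range in Dixon's test. Chance singles out about 1 of 20 groups where values are independent and normally distributed. Here 27 of 245 groups tested were singled out, where chance gives about 12.2, and 9 of them were in MI replicate 3 and 8 in MI replicate 2. The figure of 12.2 is a rough guide only. Values were taken as normalised reads without logs, and several of these genes move together.

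In MI replicate 3 the normalised reads of fat, mesothelium, fast muscle and B cell genes lay above the other MI libraries: Cfd 9299.5 against 98.6 to 1014, Car3 9913 against 117 to 717, Cidec 1546 against 33.2 to 194, Upk3b 1846 against 83.5 to 125, Upk1b 519 against 34.6 to 90.1, Lrrn4 617 against 39.1 to 43.6, Tnnt3 2574 against 172 to 219, Jchain 1453 against 64.2 to 113 and Cxcl13 639.9 against 45.1 to 51.5. MI replicate 2 lay apart from the other MI libraries with Nppa at 251068 against 407622 to 418466, Kcnv2 at 1065 against 338 to 364, Tbx20 at 20225 against 23743 to 24438, Pfkp at 17799 against 20753 to 21346, S100a8 at 665 against 149.9 to 206, S100a9 at 1091 against 239.7 to 286, Gm6093 at 329 against 32.1 to 62.0 and XLOC_016573 at 833 against 376 to 390.1. MI replicate 1 was highest of its group in Meg3 with 9272 against 5498 to 6074, in Mmp12 with 4204 against 968 to 1503 and in Gpnmb with 5978 against 1564 to 2168. Among Sham libraries, replicate 4 stood out with Myl7 at 118 against 2.27 to 12.5, Myl4 at 460.4 against 173 to 184 and Ccr7 at 37.8 against 10.2 to 14.3, replicate 3 with Fos at 753 against 105 to 183 and Comp at 481 against 206 to 244, and replicate 1 with Flt3 at 32.2 against 18.2 to 19.3 and Upk1b at 31.0 against 6.31 to 9.11.

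Pieces of other tissue in some samples are a candidate explanation for the spread of atrial and fat markers among MI libraries. As fixed beforehand, the test asked whether the markers of a tissue order the 4 MI libraries alike: Kendall's W was 0.136 over 5 atrial markers (permutation p = 0.656) and 0.706 over 7 fat markers (permutation p = 6.0e-04). The atrial bound was ill chosen, because Nr2f1 and Nr2f2 stood in Sham at up to 464 and 2089 normalised reads, as Cidea did at up to 3645, and such levels hide a small addition. Without these the 3 atrial and the 6 fat markers each gave W = 1, in different orders (permutation p = 0.0018 and 1.0e-04, the latter the smallest that the permutations can give), and 21 of 24 tested fat, mesothelium and skeletal muscle markers were highest in MI replicate 3, so added tissue and expression within the border zone cannot be told apart for these genes. Atrial tissue as the source of the rise of Nppa is argued against: Nppa was 23.6 times the Sham mean in MI replicate 1, whose Sln and Myl7 lay within the Sham range, and lowest in MI replicate 2, which had the most Myl7.

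The smaller share of chrM reads in MI might come from dilution by RNA of cells other than cardiomyocytes. Against that as the whole cause, the log2 ratio of chrM reads to reads of the sarcomere list, which dilution alone would leave in place, differed by -0.364 between MI and Sham (SD 0.077 in Sham and 0.071 in MI), below Sham in all 4 MI libraries. The ratio of nuclear oxidative phosphorylation transcripts to the same list differed by -0.386, which restates the fall of that list in the report and decides nothing about a joint fall of transcripts of both genomes, so that stays open. The reanalysis remark of the Sham samples coincides with the groups, so a difference in RNA preparation cannot be told apart from the effect of infarction.

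Falls made up more of the calls at unannotated loci than at protein-coding genes; of tested loci 16.7% against 21.7% fell with all levels pooled, but the unannotated percentage was the higher in each of the 5 bins of level (8.68% against 4.86% in the lowest, 41.2% against 28.1% in the highest). For loci past the filter on low values, the values below argue against each explanation as the whole cause of the larger share among calls. With reads outside chrM thinned to equal depth the gap in the percentage of calls that fell was 19.6 points (Fisher's exact p = 1.04e-25), and for unannotated loci at least 100 kb from any annotated locus, where reads running over from a known gene are least likely, it was 33.6 points over 154 calls (Fisher's exact p = 4.32e-17). Called protein-coding genes matched on mean level fell in 18.7% of cases (median of 1000 draws), and the unannotated share lay 40.9 points above the highest draw. The draws match level only. Falls made up 14.3% of coding calls in the lowest bin and 62.2% in the highest, so the size of this gap depends on the coding genes drawn. Loci below the filter on low values were not among the draws. Without that filter the gap between the classes was 5.99 points, against 16.8 in the main test, and the filter's part in it was not tested. What stays open is how the loci were assembled and from which libraries, which was not tested, and a biological difference between infarcted and sham hearts, for which no test was run.

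Chance can be excluded for the counts of loci at a share of splits under 0.05, though only by the smallest share that 4 against 4 can give. Of the 35 splits of the 8 samples into 4 and 4, 1, the real split, gave as many loci past the threshold (7854, highest other 0); the same held for loci changed at least 2-fold (2458, highest other 0) and for unannotated loci (1023, highest other 0), each with 1 split. In every other split the real difference adds to the spread within the groups, so the size of the gap to these other counts is a weak reference. Chance cannot be excluded for the number of gene lists past camera with a preset correlation: 8 of the 35 splits gave at least the real 24, and the highest other gave 28. This count is a weak measure of chance: the 7 other splits with as many each hold 3 libraries of a real group and so carry part of the real difference, while the 18 splits with 2 libraries of each group gave 1 to 15 lists.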

How the results depend on the processing

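Scaling to the total outside chrM, thinning to equal depth and the distance limit on unannotated loci were chosen after the data were seen; the other alternatives were fixed before the data were examined. All counts below are loci higher and lower in MI, from limma unless another tool is named. Total scaling gave 8569 and 1493 over all loci, 2773 and 378 at 2-fold or more and 689 and 380 unannotated, and total scaling without chrM 6389 and 2142, with 466 lower at 2-fold or more; 1 constant per library makes these shifts. Testing against a fold of 1.2 left 2323 and 1485. A mean of at least 50 tests fewer loci and left 1138 and 395 at 2-fold or more and 122 and 324 unannotated. Without a filter 701 unannotated loci rose and 725 fell, and the cause was not tested. Loci of 2 or more exons held 160 and 367 of the unannotated calls, those at least 10 kb from an annotated locus 143 and 378. Thinning to equal depth gave 3824 and 3695 over all loci, 1548 and 619 at 2-fold or more and 265 and 532 unannotated. Camera with an estimated correlation passed 0 lists in either direction, while fry passed 21 higher and 7 lower, and camera with total scaling 15 and 5. DESeq2 called 8447 loci and voom 7830.

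Leaving out each library in turn gave 3324 to 3976 higher and 3193 to 3897 lower over all loci, 1532 to 1832 and 613 to 936 at 2-fold or more, 226 to 346 and 501 to 731 unannotated (the fewest rises, 226, without MI replicate 1), and 20 to 21 and 4 to 5 lists. Over the alternatives counted here, the gap in percentage called between unannotated and protein-coding loci ran from -34.0 to -6.86 points. The gap in falls among calls ran from 5.99, without a filter on low values, to 28.1. The Spearman coefficient between neighbours ran from 0.172 to 0.410, and none of these changed side of the threshold. These ranges leave out the bins of level and some subsets by distance and strand. In the bins the gap in calling was not shown from 200 to 1000 and was turned round over 1000. The coefficient was 0.119 over 10 kb, 0.116 over 100 kb and 0.124 on the same strand. Across total, total without chrM, TMM and upper-quartile scaling the gap in falls was at least 15.7 points; scaling was dropped from the explanations weighed for that gap after this value was seen. For the 125 loci under the rule for named genes, 2630 of 2725 values under alternatives kept direction and side of the threshold, 84 lost the call and 10 gained it (4 for H19 and 6 for Uty); Uty turned to 0.083 with total scaling, which adds about 0.31 to every log2 difference. Replicate numbers are shared by the groups: with the replicate block 4152 loci rose and 4056 fell, but same-numbered samples correlated between -0.0009 and 0.272 in their deviations and 5 of 8 correlated best with their own number, a hint from the data. Since 1 of the 4 same-numbered pairs did not correlate and no label ties the numbers to a shared animal, batch or day, the numbers were not taken to pair the samples. With the block H19 passed as higher and Uty as lower, and 22 lists passed as higher and 5 as lower, the added ones being immediate early, atrial and erythrocyte genes.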

Other observations

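Some loci absent from the deposited annotation carry the exon structure of genes in the later GENCODE release, coding ones included. Of 3908 unannotated loci tested, 224 had such a match, of which 37 rose and 69 fell in MI by the same limma fit. Mylk4, a myosin light chain kinase family gene, was the most abundant of those described here and fell from 68727 ± 15763 to 26345 ± 6009.9 (log2 difference -1.38 ± 0.19, adjusted p = 2.64e-04). Klhl33 fell from 6214 ± 627 to 1856 ± 383 (log2 difference -1.76 ± 0.14, adjusted p = 1.05e-05), and Sbk2, a kinase gene, by a log2 difference of -1.55 ± 0.20. Hephl1, a ferroxidase related to hephaestin, rose from 0.867 ± 1.09 to 31.9 ± 12.1 (log2 difference 4.24 ± 0.51, adjusted p = 1.27e-04). Among later non-coding genes Gm36827 fell from 10578 ± 1314 to 4362 ± 791 (log2 difference -1.29 ± 0.13, adjusted p = 4.16e-05) and Gm31600 by a log2 difference of -2.71 ± 0.25. These genes were chosen after their values were seen.

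Joined where they lay within 10 kb of each other, the 3908 tested unannotated loci made 2628 clusters. The 371 unannotated loci that rose fell into 317 clusters and the 652 that fell into 491, and 6 clusters held both; whether calls cluster more than tested loci was not tested. Of the 3908 tested, 2400 lay within 10 kb of an annotated locus, where 228 rose and 274 fell. The 10 most abundant loci outside chrM took 13.6 ± 0.327% of the reads outside chrM in Sham and 10.6 ± 0.570% in MI (n = 4 each, 2-sided exact permutation p = 0.0286, the smallest possible). Unannotated loci took 0.848 ± 0.158% in Sham and 0.724 ± 0.0955% in MI (exact permutation p = 0.229), a difference within the spread between libraries.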
